A study of Mus musculus with 7 samples.

How the data were processed

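The series holds 7 mouse embryonic stem cell RIP-seq libraries, from nuclear lysates incubated with an anti-Ezh2 antibody (5 wild-type, 1 Ezh2-null) or with normal rabbit IgG (1 wild-type), recovered on protein A beads and converted to cDNA by template switching, per the labels' protocols. The deposited table has a row for each distinct read sequence and its read count, without a header, and the authors' counts are not scaled to depth. How the authors collapsed or filtered the reads is not given in the sources used here, nor is the aligner. The name under which the table was deposited was not used as a source. The submitters' processing notes name the genome build mm9, but the table has no coordinates. The table was checked to hold each sequence once, with lengths from 12 to 36 bases and of 40 bases. Because neither a header nor a label ties its count column to a library, it was treated as 1 pool, with no SD and no replicate number, and tests between groups, their scaling alternatives and the agreement between cultures were left out.

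Reads were matched to the GENCODE M21 transcripts (GRCm38) with bwa 0.7.19, with up to 2 mismatches over the matched part of the read, no gaps and up to 1000 listed placements. Coordinates given are those of GRCm38. In 1097932 distinct 40-base sequences the mismatch rate was 38.5% at base 1 and fell to 10.9% at base 6, against 1.78% at the later bases, so the leading 6 bases were left out before matching, a choice made after the data had been seen. At least 20 bases had to remain, so that reads of 26 bases or more were searched. Reads of abundant mRNAs are the reverse complement of the RNA, and orientation is given for the RNA. A read was given to a gene when its best placements lay in RNA-sense orientation on that gene alone, with antisense placements allowed only on genes that overlap it on the other strand, or in antisense orientation on a single gene. This rule favours the sense gene where genes overlap on opposite strands. Introns, intergenic sequence and most nuclear-encoded ribosomal RNA outside the annotated 18S-like locus are not in the transcript set and were not searched. The cells carry a M. castaneus-derived genome in part, per the labels, so that strain differences can use up allowed mismatches. On 40000 simulated reads with 0 to 2 mismatches, 87.5% were returned to their own gene and strand, 11.0% matched several genes, 1.28% were given to an overlapping gene on the other strand and 0.113% to a wrong gene or strand. The simulated reads were drawn from the same transcripts, so wrong assignment of reads from outside them was not measured.

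Reads per gene are sense reads, with exact Poisson 95% intervals. RPKM values were computed from the deposited counts as sense reads per kb of merged exons and 1000000 searched reads. Percentages carry exact Clopper-Pearson 95% intervals from scipy 1.17.1, and a count of 0 is given a limit of 3 counts. A gene's antisense share was called above 50% when its interval lay above 50%, among genes with at least 50 reads. A start position is the transcript base at the 5-prime end of the matched part of a read. The 15 gene lists, with 339 symbols of which 324 were in the annotation, were fixed before the data were examined. They cover the X-inactivation centre, imprinted noncoding and coding genes, Polycomb complexes, pluripotency, developmental regulators targeted by Polycomb, Hox noncoding RNAs, nuclear noncoding RNAs, ribosomal protein mRNAs, mitochondrial genes, histones, housekeeping mRNAs, spliceosomal and small nucleolar RNAs, fibroblasts and early differentiation. Each list's median RPKM was placed among 10000 random lists of the same size matched on 10 bins of exonic length, as a description of this table. The random lists were drawn from all 55341 annotated gene symbols, of which 27805 had a read and 6981 at least 50 sense reads. A high percentile thus sets a list against many genes with few or no reads, not against expressed genes. In 100 simulated lists of 20 genes, 5% of unchanged lists fell outside the middle 95%, and 100% of raised lists fell above it. RPKM values were first permuted among all genes within length bins, so the 5% does not cover differences between gene types. The raise was large, so the 100% does not tell how smaller differences would be found.

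The named genes follow a rule set before the data were examined. It takes the 10 genes with most sense reads and the 10 with most antisense reads, the 4 highest of each list or all of a list of up to 12 genes, and Xist, Tsix, Kcnq1ot1, Meg3, Nespas, Malat1, Neat1, Ezh2, Pou5f1 and Actb. Some genes that the rule takes are not reported here. Alternatives counted each distinct sequence or start position once, allowed no mismatch, took reads of at least 30 bases, required no other gene within 1 further mismatch, or used all placements, other minima of 20 and 200 reads, genes without an overlapping gene on the other strand, and random lists matched on gene type. Alternatives added after the data had been seen were whole reads, 36-base or 40-base reads alone, random lists matched on length and gene type, lists without each gene's highest start position, and the pseudocounts and minima of the read length comparison. Matching on whole gene bodies was not run. Figures were drawn with matplotlib 3.10.9, and scripts were run with python 3.11.15 and numpy 2.4.6.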

Results

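The series profiled RNA that came down with Ezh2, the histone H3 lysine methyltransferase of Polycomb repressive complex PRC2, from nuclei of mouse embryonic stem cells grown with LIF. In such RNA immunoprecipitation sequencing (RIP-seq) an antibody pulls a protein out of a nuclear lysate and the RNA that comes with it is converted to cDNA and sequenced. The labels describe 7 libraries. In 5 of them an anti-Ezh2 antibody was used on wild-type cells, in 1 the same antibody was used on Ezh2-null cells, and in 1 normal rabbit IgG was used on wild-type cells. Of the 5 Ezh2 libraries, 1 is labelled a technical replicate, 1 a biological replicate, and 2 are deeper sequencing runs of 2 lanes each. The values used here come from 1 table of distinct read sequences with a read count for each, which holds 34072479 reads of 6540936 sequences and which no label ties to any of the 7 libraries. The planned comparisons of Ezh2 with IgG and with Ezh2-null, and of separate Ezh2 cultures with each other, were therefore not made. What follows describes the RNA in this table, without replicates, and no value below is an enrichment over a control.

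RNA from the ribosomal DNA, mitochondrial RNA and messenger RNA made up most of what could be assigned. Of 31529044 reads long enough to be searched, 36.04% were assigned to a single annotated gene, 11.3% matched several genes equally well and 52.6% matched no annotated transcript. Among the assigned reads, 59.8% belonged to nuclear genes outside the ribosomal DNA-like locus, 28.6% to that locus, and 11.7% to mitochondrial genes. That locus is an 18S-like pair of overlapping genes on chromosome 17 (GRCm38), Gm42418 at 39846958 to 39848788 on the plus strand and the rRNA gene CT010467.1 at 39846353 to 39848827 on the minus strand. Gm42418 had 2596236 sense reads and CT010467.1 had 653849 antisense reads, so that both counts are RNA of the plus strand. Plus-strand reads that match both genes equally go to Gm42418 by the rule. The reads of CT010467.1 therefore need not be 18S sequence, and 18S-like below means reads of either gene. The searched reads in RNA-sense orientation to a single gene were 28.2% of the total (95% Clopper-Pearson interval 28.189 to 28.22), and those in antisense orientation 7.84% (7.8279 to 7.8467). The antisense reads include the 653849 of CT010467.1, which are RNA of the same strand as the sense reads of Gm42418. All intervals given here cover counting error only and take each read as independent, because PCR copies cannot be told from separate molecules. Where reads are copies, the intervals are too narrow. The authors' filtering of reads is not known from the sources used here. The shares of 18S-like, mitochondrial and nuclear reads are therefore those of this table alone.

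18S-like reads differed between the read lengths held in the table. Of the 36-base reads, 22.9% were 18S-like, against 7.31% of the 40-base reads. Among 18S-like reads of 36 bases, 52.0% matched the reference over their full length without a mismatch (51.94 to 52.11), and among those of 40 bases 0.437% did (0.4279 to 0.4471). Reads of other nuclear genes gave 35.6% and 37.5%, and mitochondrial reads 39.7% and 44.1%, at 36 and 40 bases.

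**Figure D1:**
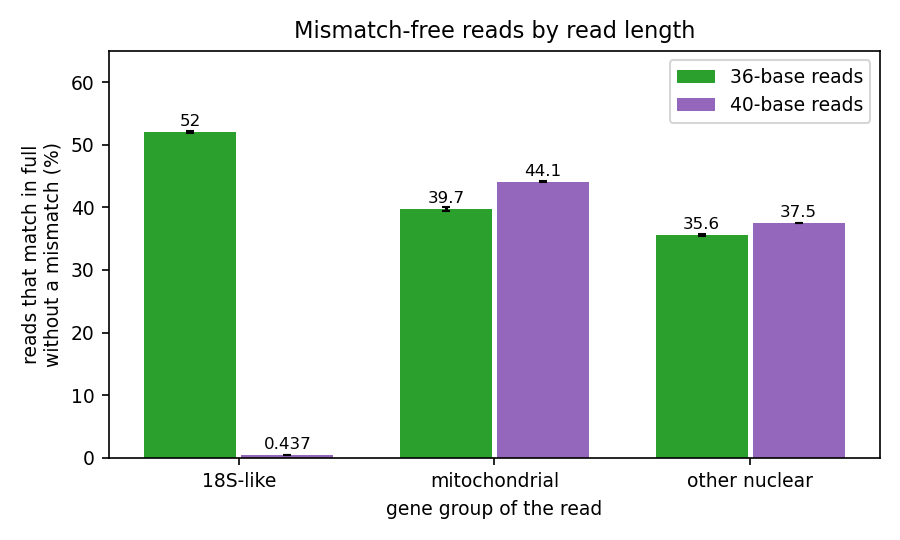
Percent of reads assigned to 18S-like, mitochondrial and other nuclear genes that match a transcript over their full length without a mismatch, for 36-base and 40-base reads (bars, with 95% Clopper-Pearson intervals). The 40-base 18S-like reads stand at 0.437%, while the other 5 bars lie between 35.6% and 52.0%.

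Serbp1, which encodes an mRNA-binding protein, had the most reads of any nuclear gene outside the 18S-like locus, with 727106 sense reads (Poisson 95% interval 725435.7 to 728779.2). It was followed by Eif3a, a translation initiation factor subunit, with 203314 sense reads, by Bms1, a ribosome biogenesis factor, with 133498, and by Malat1, a nuclear-retained noncoding RNA, with 111363. Srsf11, a splicing factor, had 85015, Hsp90ab1, a cytosolic chaperone, had 82777, and Mgea5, the O-GlcNAcase gene, had 74869. Together with mt-Nd6 at 153356, mt-Rnr2 at 93891 and Gm42418 these were the 10 genes with most sense reads. Serbp1 alone took 12.4% of nuclear sense reads and the top 100 nuclear genes took 51.4%.

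The high counts rested on few start positions. In Serbp1, 161504 of the reads started at 1 base of the mRNA, which was 22.2% of its total, and its reads covered 795 start positions. Malat1 was covered at 1326 positions, more than any other nuclear gene, and its highest position held 7.35% of its reads. In Mgea5 a single position held 36214 reads. Over all nuclear genes, 3297 of 337983 sense start positions, or 0.976%, held the upper 50% of the reads. Counts of start positions are given below for some of the genes, and counts of reads alone do not tell how many positions they rest on.

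At the X-inactivation centre, RNA of both strands of the Xist/Tsix locus was present. Xist, the noncoding RNA that coats the inactive X chromosome (chromosome X, 103460366 to 103483254, minus strand, GRCm38), had 773 sense reads at 111 start positions and 1069 antisense reads at 188 positions. Tsix, its antisense repressor (103431517 to 103484957, plus strand), had 911 sense reads at 88 positions and 84 antisense reads. Within the body of Xist, 67.7% of the 1621 plus-strand and 773 minus-strand reads were in the orientation of Tsix (65.8 to 69.6). For the locus as a whole the share in that orientation was 71.9% in 40-base reads and 54.8% in 36-base reads. The antisense share of Xist was 58.0% by reads, 62.9% by start positions, 49.2% by distinct sequences and 38.01% in 36-base reads alone, so that its side of 50% depended on the counting. These shares leave out plus-strand reads that the rule gave to Tsix. With those reads included, the plus strand led within Xist by start positions too, with 230 against 111.

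**Figure D2:**
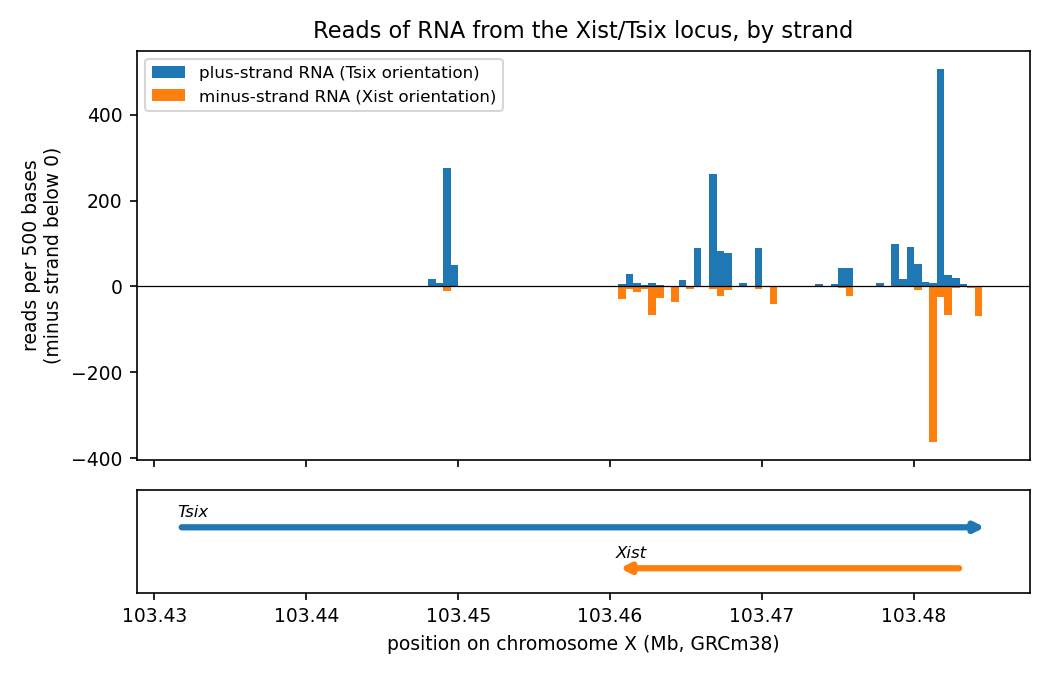
Reads per 500-base bin over the Xist/Tsix locus on chromosome X (GRCm38 coordinates in Mb on the horizontal axis). Bars above 0 are plus-strand RNA, in the orientation of Tsix (1980 reads), and bars below 0 are minus-strand RNA, in the orientation of Xist (857 reads). Arrows give the annotated gene bodies and their direction.

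Among the other genes of the centre, Rlim, the ubiquitin ligase that activates Xist, had 3296 sense reads, Nap1l2 683, the noncoding Ftx 140, Chic1 93, and the noncoding Jpx 30 sense and 49 antisense reads. Tsx had 2 reads. Cdx4 and Zcchc13 had 0 of 31529044 searched reads, where a count of 0 allows up to 3 reads. The list median of 0.435 sense reads per kb of exon and 1000000 searched reads (RPKM) stood at percentile 96.7 of 10000 random gene lists matched on exonic length, within the middle 95%, and at 99.6 when random lists were matched on gene type instead. Here and below, random lists were drawn from all 55341 annotated symbols, of which 6981 had at least 50 sense reads.

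RNAs of the imprinted noncoding list, in which Mcts2 is annotated as a coding gene, were present at widely different levels. Kcnq1ot1, the antisense RNA of the Kcnq1 domain, had 4877 sense reads at 371 positions (4741 to 5016), Rian 3030, H19 1613, Meg3 1037 at 155 positions, Snhg14 826 and Mirg 127. Nespas, the antisense RNA of the Gnas locus, had 39 sense reads (27.7 to 53.3), Airn 14 on each strand with 13 of the sense reads at 1 position, Peg13 11 sense and 30 antisense, Mcts2 6, and Nctc1 0. The list median of 0.552 RPKM stood at percentile 98.5, and at 92.9, within the middle 95%, when reads with several equal placements were included. Imprinted coding genes did not stand apart as a list, with a median of 0.208 RPKM at percentile 84.6. Their highest members were Igf2r with 2153 sense reads, Peg10 with 812, Peg3 with 640 and Inpp5f with 571.

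Transcripts of the Polycomb machinery itself were above random lists. Ezh2 had 12795 sense reads at 325 positions, Jarid2 1478, Suz12 1291 and Rbbp7 1234, and 17 of the 30 listed complex members had at least 50 sense reads. The list median was 0.558 RPKM, at percentile 99.9. Developmental regulators known as Polycomb targets did not stand apart from random lists, with 4 of 40 genes at 50 or more sense reads and a list median of 0.0489 RPKM at percentile 35.5. Among the highest were Irx3 with 79 sense reads, Tbx5 with 63 and Hes1 with 61, of which 41 lay at 1 position. The 8 noncoding RNAs of the Hox clusters had 17 sense reads in all, with 6 on Hoxd3os1, 4 on Hotair, 4 on Hoxb5os, 2 on Hoxaas3, 1 on Hotairm1, and 0 on Hottip, Hoxa11os and Hoxaas2, and 20 antisense reads, with 13 on Hoxaas3 at 1 position and 7 on Hoxd3os1. Their median was 0.0265 RPKM, at percentile 50.8.

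Pluripotency genes stood high, with 23 of 30 at 50 or more sense reads and a list median of 2.33 RPKM, above all 10000 random lists. Lefty2, a Nodal antagonist, had 66761 sense reads, L1td1 29926, the Nodal co-receptor gene Tdgf1 4569 and Tet1 4002, of which 2116 lay at 1 position. Pou5f1, the core pluripotency factor Oct4, had 429 sense and 368 antisense reads. Early differentiation genes had a median of 0.0693 RPKM at percentile 60.0, led by Nes with 205 sense reads, Otx2 with 133, Eomes with 60 (38 at 1 position) and Sox1 with 32 (29 at 1 position). Genes of fibroblasts and their matrix also stood above all random lists, at a median of 3.46 RPKM, and 13 of the 15 had at least 50 sense reads. Postn had 5268, the collagen genes Col1a1 and Col1a2 had 3775 and 1920, and the smooth muscle actin gene Acta2 had 3261, of which 2765 were 36-base and 422 were 40-base reads. The labels name no feeder cells.

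Nuclear noncoding RNAs (median 1.20 RPKM), housekeeping mRNAs (4.55), cytosolic ribosomal protein mRNAs (0.830), mitochondrial genes (252) and the list of replication-dependent histones (0.383), which also took in the replication-independent H1f0, were each above all 10000 random lists. For the mitochondrial and histone lists the random lists had a median of 0 RPKM, so that the rank itself says little about level. Of 27 listed histone symbols, 16 were in the annotation and 5 had at least 50 sense reads. The histone list stood at percentile 97.8 when random lists were matched on gene type, and at 99.97 with length and type. Neat1, the scaffold RNA of paraspeckles, had 785 sense reads, well under the count of Malat1. Among housekeeping genes, Hsp90ab1 was followed by Eef2 with 36769, Actb with 18453 and Ncl with 8181 sense reads. Rpsa with 6837 (3073 at 1 position), Rpl4 with 1960, Rps24 with 882 and Rpl5 with 849 led the ribosomal protein genes, and Hist1h1d with 334, Hist1h1c with 146, Hist1h2bc with 66 and H1f0 with 65 led the histone list. The list of spliceosomal and small nucleolar RNAs had a median of 0, as did the random lists, so that its percentile of 50 comes from ties and gives no rank. It stood at 100 when reads with several equal placements were included. Scarna2 had 59 sense reads, Rnu3a 9, Snora73b 3 and Scarna6 1. Multicopy RNAs and mRNAs with many processed pseudogenes lose reads to the class of several genes, so that low counts in these families are uncertain.

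**Figure D3:**
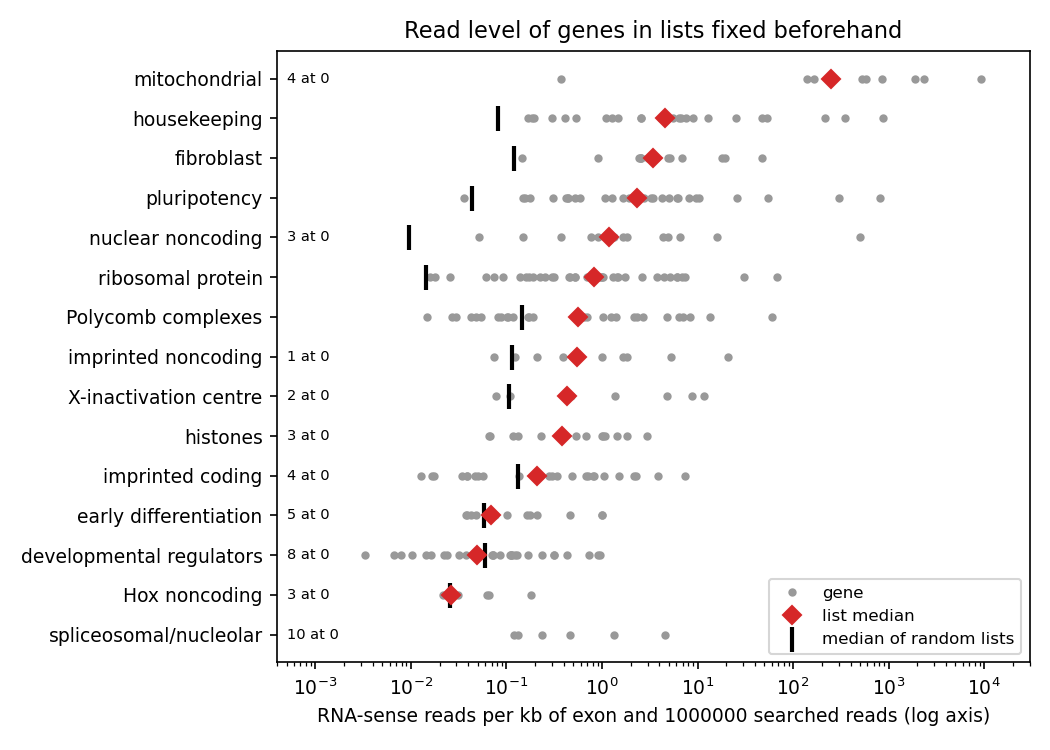
Level of each gene in the 15 lists, in RNA-sense reads per kb of exon and 1000000 searched reads on a log axis (grey points), with the list median (red diamond) and the median of 10000 random lists matched on exonic length (black bar). Genes without a sense read are counted at the left, and medians of 0 are not drawn. The pluripotency median lies at 2.33 and that of the developmental regulators at 0.0489.

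Most reads of nuclear genes were in RNA-sense orientation. Over nuclear genes outside the 18S-like locus, 13.7% of 6789401 reads were antisense (13.64 to 13.69), and 25.02% of start positions were. By reads the antisense share was 0.0349% in Serbp1, 0.215% in Eif3a, 1.85% in Actb, 29.5% in Ncl and 43.2% in Rpl4, and by start positions 5.69%, 7.13%, 22.3%, 15.9% and 28.4%. Kcnq1ot1 had 18.01% antisense reads, Meg3 12.4%, Neat1 13.8%, Malat1 3.83% and Ezh2 7.78%. Of 8908 nuclear genes with at least 50 reads, 1398 had an antisense share whose interval lay above 50%, and 390 did when each start position was counted once. Counting positions or distinct sequences leaves fewer counts per gene, so that intervals are wider and fewer genes can lie above 50%. The number of genes above 50% was 806 with each distinct sequence counted once. With other sets of genes tested it was 814 of 4974 among genes that overlap no gene on the other strand (16.4%, against 15.7% as reported), 2565 of 13642 at a minimum of 20 reads (18.8%), 442 of 3632 at a minimum of 200 reads (12.2%), 246 of 2057 in 36-base reads (11.96%) and 1147 of 7872 in 40-base reads (14.6%).

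The genes with most antisense reads were the 18S-like CT010467.1, 7 mitochondrial genes that are annotated on the plus strand, and the nuclear genes Tro and N4bp2. The antisense reads of CT010467.1 are RNA of the same strand as the sense reads of Gm42418. In Tro 44255 of 44590 antisense reads, and in N4bp2 32347 of 37485, started at 1 position. By start positions, the antisense share was 37.3% in Tro and 24.7% in N4bp2, both below 50%. Mitochondrial genes had 885001 antisense and 432759 sense reads in the 15-gene list, an antisense share of 67.2% (67.08 to 67.24), and 58.9% by start positions. In that list mt-Co2, mt-Co3 and mt-Nd4l had 0 reads on either strand, mt-Nd3 0 sense and 9 antisense, and mt-Atp6 8 sense and 52 antisense. Reads that matched several genes are not in these counts, so the share need not hold for every mitochondrial gene. mt-Nd5, a subunit of respiratory complex I, had 292902 antisense and 48523 sense reads. The antisense counts were 167844 for mt-Co1, of which 146498 lay at 1 position, 106715 for mt-Cytb, 83747 for mt-Nd1, 81593 for mt-Nd2 and 54693 for mt-Nd4. mt-Nd6, annotated on the minus strand, had 153356 sense and 6027 antisense reads, so that its reads too were minus-strand RNA. The ribosomal RNAs mt-Rnr1 and mt-Rnr2 had more sense than antisense reads, with antisense shares of 36.1% and 23.0%, though that of mt-Rnr1 was 59.5% in 36-base reads.

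**Figure D4:**
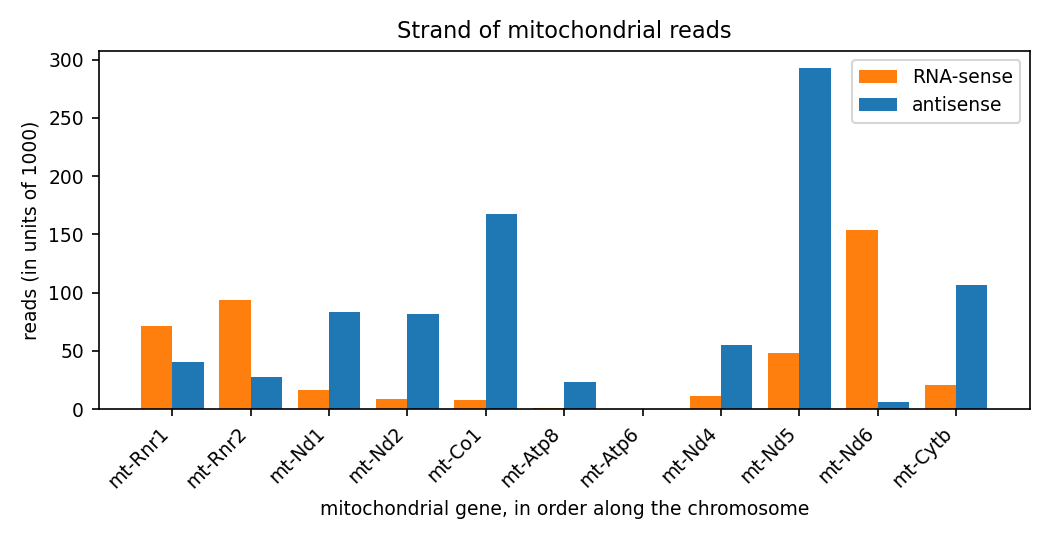
RNA-sense and antisense reads (in units of 1000, linear axis from 0) of the 11 genes of the mitochondrial list with at least 50 reads (tRNA genes are not in the list), in their order along the mitochondrial chromosome. Antisense reads exceed sense reads in mt-Nd1, mt-Nd2, mt-Co1, mt-Atp8, mt-Atp6, mt-Nd4, mt-Nd5 and mt-Cytb, and sense reads exceed antisense reads in mt-Rnr1, mt-Rnr2 and mt-Nd6.

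Within nuclear protein-coding genes the sense reads lay mostly in coding sequence. Of 5474731 such reads, 79.1% fell in coding sequence (79.09 to 79.16), 14.7% in the downstream untranslated region, 1.38% in the upstream untranslated region and 4.85% only in noncoding isoforms. By start positions these shares were 63.7%, 22.9%, 4.38% and 9.02%. Coding sequence made up 48.3% of the length of the longest coding transcripts of the genes with at least 50 reads, the downstream region 45.8% and the upstream region 5.93%. A read that fell in coding sequence of any coding isoform was counted there, and these lengths follow no such rule. The shares of reads and of length are therefore not fully alike, and part of the excess in coding sequence may come from that rule. Introns and sequence between genes were not searched.

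Chromosome 6 held 19.5% of nuclear sense reads, more than any other chromosome, and 8.11% with Serbp1 left out. Chromosome 19, with Malat1, Eif3a and Mgea5, held 9.54%, and chromosome X held 3.01%. By start positions chromosome 6 held 6.39%, and the number of positions per kb of exon was 2.91 on chromosome 6, 3.46 on chromosome 19 and 2.94 on chromosome X.

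The table pools 6252281 reads of 36 bases and 24772940 of 40 bases, with 0 reads of 37 to 39 bases, and these read lengths were compared gene by gene after the data had been seen. Across 22836 nuclear genes, log2 counts (pseudocount 1) of 36-base and 40-base reads had a Pearson correlation of 0.791 and a Spearman correlation of 0.718, where genes are not independent replicates. Of the start positions of 36-base reads, 52.7% were also seen in 40-base reads, and these positions held 82.6% of the 36-base reads. Of 675 genes with at least 1000 reads, 241 differed by more than 2-fold in their share of the 2 read lengths. The share in 36-base reads was 50.8 times that in 40-base reads for Acta2 (45.8 to 56.4), and 0.00728 times for Zfp281 (0.00363 to 0.013), the extremes of the range, of which Zfp281 was named after its values had been seen. No label ties a read length to a library.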

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

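The tests in this part were chosen after the values had been seen, except for that of the sequences with 1 mismatch, whose bound was set before its result but after the 18S-like pattern was known. In the data outside the gene counts, 1001930 reads began with the same 12 bases and are flagged because they lie outside the gene counts with no control library to set against them. Of these, 800965 were the sequence TCGTATGCCGTCTTCTGCTTGA, which is that of a commonly used sequencing adapter. In all, 2543435 reads were shorter than 26 bases and were not searched. Of the searched reads, 16590724 matched no transcript. Introns, intergenic RNA and most nuclear-encoded ribosomal RNA outside the 18S-like locus would fall in this class.

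Of the 36-base reads 22.9% were 18S-like, against 7.31% of the 40-base reads, and 52.0% and 0.437% of these had no mismatch. A general difference in mismatch rate between the read lengths is argued against, because among other nuclear genes the share without a mismatch differed by -1.89 points (36-base minus 40-base). Removal of sequences identical to ribosomal RNA from the 40-base reads alone is argued against as the whole cause, because it would leave sequences with 1 mismatch in place, while among distinct 18S-like sequences with 1 or 2 mismatches the percent with 1 mismatch was 29.3 at 36 bases and 1.15 at 40 bases, a difference of -28.2 points, 40-base minus 36-base (45.5 and 53.5 at 40 bases for mitochondrial and other nuclear genes, against 50.7 and 56.1 at 36 bases). A removal that also took sequences with 1 mismatch was thought of only from these values and stays open, untested. No biological explanation was tested.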

How the results depend on the processing

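Intervals take each read as independent, although 80.8% of reads repeat a sequence already counted, so they are narrow at this depth. Most percentages left them, and the cause was not tested unless given. Whole reads, single read lengths, matching on length and type together, the pseudocounts, the searched-only and gene-left-out values, and for strand and lists the mismatch, placement and read length settings, were added after the data had been seen. The gene body alternatives were not run, because introns were not in the reference used, and those of the Ezh2 against control comparison and of the separate cultures were not run, because the table is not tied to libraries. No paired analysis was possible because the single count column carries no replicate number.

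The share of searched reads given to 1 gene was 36.04%, and became 27.0% by distinct sequences, 30.8% without mismatches, 35.99% for reads of at least 30 bases, 33.4% with stricter placement, 30.1% with whole reads, 36.5% in 36-base and 35.96% in 40-base reads. The nuclear antisense share of 13.7% became 15.8% by distinct sequences, 25.02% by start positions, 15.04% among genes without an overlapping gene, 11.3% without mismatches, 12.7% with stricter placement, 13.23% with whole reads, 17.1% in 36-base and 13.21% in 40-base reads. The 1398 genes with more antisense reads of 8908 tested became 806 by distinct sequences and 390 by start positions. With other numbers of genes tested they became 2565 of 13642 and 442 of 3632 at minima of 20 and 200 reads, 814 of 4974 without overlapping genes, 246 of 2057 in 36-base and 1147 of 7872 in 40-base reads. The coding sequence share of 79.1% became 76.4% by distinct sequences, 63.7% by start positions and 79.5% with stricter placement. Chromosome 6 went from 19.5% to 10.4% by distinct sequences, 6.39% by start positions, 20.1% with stricter placement and 8.11% without Serbp1. The correlation of read lengths of 0.791 became 0.747 and 0.859 with pseudocounts 0.5 and 10. Reads that repeat a sequence already counted were 80.8% of the table and 79.9% of searched reads.

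The X-inactivation centre list moved from percentile 96.7 to above the middle 95% by distinct sequences (98.4), start positions (98.6), gene type (99.6), length and type (99.3), no mismatch (97.8), 36-base reads (99.5) and all placements (98.5). With all placements the imprinted noncoding list fell to 92.9, and the spliceosomal list, tied with random lists at a median of 0 as reported, stood at 100. All other lists stayed on their side of the middle 95% under the settings run.

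The antisense share crossed 50% by distinct sequences in Xist (49.2%), Inpp5f (41.6%), N4bp2 (37.7%) and Sox1 (53.8%), by start positions in Inpp5f (38.5%), N4bp2 (24.7%), Tro (37.3%) and Sox1 (66.7%), in 36-base reads in Xist (38.01%), Inpp5f (22.8%), N4bp2 (32.9%), mt-Rnr1 (59.5%) and Hes1 (76.9%), in 40-base reads in H1f0 (53.8%), and with stricter placement in Pou5f1 (54.5%). Of the 728 values of scaled reads of named genes under other settings, 380 left the Poisson interval.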

Other observations

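The genes named in this part were chosen after their values had been seen. By start positions, Fn1, the fibronectin gene, followed Malat1 among nuclear genes, with 39714 sense reads at 1108 positions. Myh9, the nonmuscle myosin heavy chain gene, came next with 889 positions, then Serbp1 with 795, Lrp1 with 670, Eif3a with 651, Bms1 with 622, Thbs1 with 604 and Cald1 with 589.

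In 369 nuclear genes with at least 50 reads the antisense share lay above 50% by its interval both by reads and by start positions. Xist had the most antisense positions of these. The pluripotency gene Klf5 had 2374 antisense reads at 90 positions against 366 sense reads at 57 positions. Prr36 had 1997 antisense reads at 94 positions and 17 sense reads, the noncoding 4930452G13Rik had 4158 at 77 positions and 5 sense reads, and Pcbp1 had 2851 at 55 positions and 121 sense reads.

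All tests of the fibroblast list were chosen after its values had been seen. The list stood above random lists, and a general excess of long or coding transcripts is argued against by its percentile of 100 among random lists matched on length and gene type, as are PCR copies by its percentile of 100 with each start position counted once. RNA of fibroblasts in the culture stays open, as does expression of the same genes by the stem cells or their differentiated progeny, since the count of 13 of the 15 members with at least 50 sense reads restates that the list is high and is what each of these would give. Postn stood at 19.2 RPKM and Col1a1 at 18.2, and Acta2 at 47.1 with 2765 of its 3261 sense reads at 36 bases and 422 at 40 bases. None of the 15 genes is in another of the lists.

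The matched RNA was rich in purines, with mean excesses over each gene's own transcript of 8 points in the 6 bases at the leading read bases left out of matching (SD over genes 6.27), 5.15 points in the 28 bases beside them (SD 5.34), and 2.96 points upstream (SD 3.96) and 2.84 points downstream (SD 4.31) more than 100 bases away. In coding genes, 61.2% of its bases were A or G by reads and 56.3% by start positions, against 50.6% in the transcripts of the same genes. PCR copies as the whole cause, a test chosen after the values had been seen, are argued against by the excess of 5.64 points by start positions. A preference for the leading 6 bases alone is argued against by the 28 bases beside them. The bound of that test was set before its result but after the excess was known. Those 28 bases were richer in purines than the bases beside every occurrence of the same 6, by a mean of 4.24 points (SD over genes 4.80). Of 1448 genes, 84.3% lay above 0. Whether a primer gave the leading 6 bases is not shown here. Location in coding sequence as the whole cause is argued against by 83.2% of 870 genes whose positions in coding sequence were richer in purines than that sequence, although the mean excess was smaller there, at 3.71 points (SD 4.37). A preference of the immunoprecipitation, of fragmentation or of cDNA synthesis for purine-rich RNA may each give such a pattern and stays open, since no control library could be compared.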
